A study of Mus musculus with 20 samples.

How the data were processed

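Single-cell RNA was measured in 20 libraries from orthotopic Py8119 mammary tumours of C57BL/6 mice, in 8 groups. The vehicle (Captisol) and RK20449 libraries (3 each) were made with the 10x Chromium 3′ v2 workflow and all others with v3, per the labels' protocols. The other groups were untreated tumours at day 10 and day 14 (2 each), tumours on HckKO mice and their wild-type controls (WT_KO; 3 each), and tumours on HckCA mice and their wild-type controls (WT_CA; 2 each). Tumours were minced, digested, strained and freed of red cells, and frozen aliquots were thawed for capture, per the labels' protocols.

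The deposited matrices hold whole-number UMI counts per gene and cell, made with bcl2fastq and Cell Ranger 7.0.0 on the mm10 genome, per the submitters' processing notes. The files read here held no cell annotation. Per the file headers, each matrix is an integer count matrix from Cell Ranger. The feature list named 32285 genes, of which 32158 were found in GENCODE vM21, which gave coordinates. The files held 122845 barcodes, 8873 to 11110 per library in the libraries labelled as about 9000 captured cells and 2959 to 7383 in those labelled as about 6000.

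Barcodes were kept with at least 500 UMIs, at least 200 genes and under 20% mitochondrial UMIs, which dropped 9108. The barcodes with the highest Scrublet scores were then removed, 0.8% for each 1000 barcodes, which took out 7288, or 2.62 to 9.17% per library. The rate was fixed in advance; the caller's own threshold marked from 1 to 454 barcodes per library. The remaining 106449 cells (2601 to 9789 per library) had a median of 3564 to 23158 UMIs per library.

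Cells of all libraries were clustered together with scanpy 1.11.5 and igraph 0.11.9: log-normalised to 10000 UMIs, 2000 variable genes chosen within libraries, 50 principal components, 15 neighbours and Leiden resolution 1. The clustering was run from 10 random starts, each to convergence, and gave 27 to 30 clusters; each cell took the class it had in most starts. In all, 86.53% of cells had the same class in every start, and 1646 had no class in most of them. A cluster took the name of a class, as "X-like", from marker genes of 20 classes. It needed at least 3 markers with a log2 fold of at least 1 over the other cells and no more leading genes of another class than of its own. Clusters low in Ptprc in which no class clearly led were compared with the clusters with Ptprc instead, and a cluster with a median under 0.333 of the UMIs of its libraries and no leading marker over the other cells stayed unnamed. In the start closest to the vote, 24 of 30 clusters had a name, and 6429 cells stayed unnamed after the vote. Unnamed cells made up 2.96% of Vehicle, 1.87% of RK20449, 12.4% of Day10, 14.1% of Day14, 7.64% of HckKO, 7.90% of WT_KO, 8.93% of HckCA and 7.73% of WT_CA cells. The naming rule was adjusted after the clusters had been seen, on their markers alone, and the vote over starts was adopted after the results of a single clustering had been seen to shift. The T cell-like cells were clustered again alone (30 components, resolution 1) for subsets.

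For each comparison, UMI counts were summed per library and class (classes with at least 20 cells in each library) and tested with edgeR 4.0.16 (R 4.3.3) on the libraries of that comparison alone: TMM factors, filterByExpr, a robust quasi-likelihood F-test (glmQLFit, glmQLFTest) and Benjamini-Hochberg adjustment over the genes tested, with adjusted p under 0.05 as passing. CPM values are a gene's UMI counts scaled to a common total of the class in each library, with the TMM factors unless said otherwise. Fold changes, with their standard errors, are edgeR's log2 estimates, the first group over the second. Shares of a class among the cells of a library were tested with the same edgeR test on cell counts, with the library's cells as offset and adjustment over the classes with at least 5 cells on average, beside a two-sided exact permutation test of the shares; that test cannot give a p under 0.1 with 3 libraries against 3, or under 0.333 with 2 against 2. Fixed gene lists (38, each with at least 3 tested genes where used) were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists tested in a class; fry was run beside it. Values given as "adjusted over the list alone" are Benjamini-Hochberg adjustments within a list.

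The groups, tests, marker genes, gene lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took, in macrophage-like cells, the 8 genes with the largest rise and the 8 with the largest fall among those passing, with a mean of at least 20 CPM and no overlap between groups, and 5 and 5 in T cell-like and tumour or mesenchymal-like cells. Predicted, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes were left out of that ranking. Where fewer than 3 genes passed, the 3 with the lowest p were named. The SRC family kinases and up to 4 members of each described list with the lowest p were named as well. The T cell subset tests, the monocyte-like gene tests, the comparison of share changes between experiments and the alternatives named as added were chosen after seeing the data.

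The alternatives were DESeq2 1.42.0 (on all genes with a count, under its own filter), RLE factors, no filter on low counts, doublets kept, stricter cell filters (at least 1000 UMIs and under 10% mitochondrial UMIs), Leiden resolution 0.5, genes at 0.25 times or more of the level of every other class only, the replicate number as a block, each library left out in turn and, for shares, TMM factors on the class counts. Added ones were each experiment clustered alone, one start of the clustering, macrophage-like and monocyte-like cells pooled, cells thinned to 2000 UMIs, the HckKO and WT_KO libraries numbered 3 left out, and the replicate numbers crossed. Same-numbered libraries deviated together, with r over 0.1 across genes in all 3 pairs, in HckKO and WT_KO T cell-like (0.198 to 0.286) and tumour or mesenchymal-like cells (0.115 to 0.584) and in RK20449 and Vehicle tumour or mesenchymal-like cells (0.114 to 0.358). Day10 2 and Day14 2 shared an unnamed cluster (755 and 375 cells, against 1 and 5 in Day10 1 and Day14 1), and r was 0.142 in T cell-like cells of these groups. The labels do not say what a number marks, so this pairing comes from the data alone. Counts were not corrected for free RNA in the droplets.

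The gene test was tested on simulated data with 200 changed genes per comparison and class. In macrophage-like cells it found 74, 77, 85 and 71% of 2-fold changes for RK20449, HckKO, HckCA and Day14 (11511, 12823, 12581 and 12868 genes simulated), with 9.19, 10.1, 6.91 and 16.0% of its calls false. The share test found 32, 60, 58 and 48% of simulated 3-fold changes in the same order. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Members of gene families with near-identical copies, such as Hspa1a and Hspa1b or the H2 genes, are uncertain where reads could be shared.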

Results

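Single-cell 3′ RNA profiles were collected from 20 Py8119 tumours, a C57BL/6 mammary carcinoma line grown in the mammary gland of mice. The groups were Vehicle (Captisol, a carrier; n = 3) and RK20449, an inhibitor of HCK and other SRC family kinases (n = 3). Others were HckKO mice (n = 3) and their wild-type controls WT_KO (n = 3), HckCA mice (n = 2), read here as carrying constitutively active Hck, and their wild-type controls WT_CA (n = 2). Untreated tumours were taken at day 10 (n = 2) and day 14 (n = 2). HCK is a SRC family kinase of myeloid cells. The libraries held 57920498 to 65591740 UMIs for Vehicle and RK20449 and 91354796 to 126281621 for Day10 and Day14. They held 75332599 to 86249042 for HckKO and WT_KO and 75236347 to 103000929 for HckCA and WT_CA. Median UMIs per cell were 3564 to 5528.5 in the v2 libraries of Vehicle and RK20449 and 9882 to 23158 in the others. After filtering, 27833 cells were macrophage-like, 45972 tumour or mesenchymal-like, 16212 monocyte-like and 5712 T cell-like, the last including NK-like cells. The largest monocyte-like cluster, of 8565 cells, was led by H2-Aa, H2-Eb1 and Cd74, genes of MHC class II. A smaller one, of 1751 cells, had Chil3, Plac8 and Ly6c2 among its leading genes.

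The RK20449 and Vehicle libraries addressed what inhibiting HCK and related kinases changed in the cells of the tumour. Macrophage-like cells of RK20449 tumours held more RNA of Vsig4, a complement receptor of resident macrophages (7.69-fold, n = 3 each), and of Abcg1, a cholesterol exporter (4.20-fold). They held less of Ccnd2, a cyclin of the G1 phase, and of Klf2, a transcription factor that restrains inflammatory activation. Of 11511 genes tested, 1169 passed in edgeR (590 up, 579 down). Of MHC class I genes 8 of 16 fell, of interferon gamma response genes 7 of 17 fell, and of lipid-associated macrophage genes 9 of 20 rose and 2 fell; these lists passed with the preset correlation (adjusted p = 0.278, 0.184 and 0.184 with an estimated correlation). In tumour or mesenchymal-like cells 2009 of 14266 genes passed, and Lgals7, a galectin of epithelial cells, was among the largest rises. Mature dendritic cell-like cells were a lower share of RK20449 than of Vehicle tumours, at 0.277% ± 0.117 (SD, n = 3) against 0.888% ± 0.243 (SD, n = 3).

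In macrophage-like cells, Vsig4 (ENSMUSG00000044206, mm10 chromosome X, 96247203 to 96293438) was at 239 ± 33.1 CPM (SD, n = 3) in RK20449 and 31.2 ± 7.59 (SD, n = 3) in Vehicle, a log2 change of 2.94 (SE 0.17, adjusted p = 5.43e-06, edgeR). Abcg1 (ENSMUSG00000024030, chromosome 17, 31057675 to 31117988) was at 73.5 ± 13.3 and 17.5 ± 2.75 CPM, a log2 change of 2.07 (SE 0.15, adjusted p = 1.2e-05). Ccnd2 (ENSMUSG00000000184, chromosome 6, 127125162 to 127152193) was at 9.53 ± 1.73 and 43.5 ± 3.00 CPM, a log2 change of -2.16 (SE 0.14, adjusted p = 5.43e-06). Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656) changed by -1.31 (SE 0.11, adjusted p = 3.31e-05). The other rises by the rule were Lyve1, a hyaluronan receptor of resident macrophages (2.52), Scd2, a fatty acid desaturase (2.15), Lpl, lipoprotein lipase (1.48), Nr1d1 (1.77) and Lyz1 (1.57). Cd36, a fatty acid scavenger receptor, rose by 1.99. The other falls were Spint1 (-1.72), Tmem119 (-1.57), Fcgr4, an activating Fc receptor (-1.35), Klra2 (-1.25), Bcl2a1a (-1.14) and Retnla (-2.41). Cd36 did not pass at Leiden resolution 0.5, without Vehicle 3 (adjusted p = 0.0644) or without RK20449 2 (0.0685). Retnla did not pass without Vehicle 1 or RK20449 1, 2 or 3 (0.0678 to 0.132), without the filter on low counts, with doublets kept or with experiments clustered alone. The count of 1169 genes became 536 without Vehicle 1, 478 without Vehicle 2 and 534 without RK20449 2. It was 610 without RK20449 3 and 1779 without the filter on low counts.

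The make-up of the macrophage-like class differed between RK20449 and Vehicle when these libraries were clustered alone, an alternative chosen after seeing the data. A macrophage-like cluster with F13a1, Folr2 and Vsig4 among its leading genes held 1961, 1410 and 2373 cells of the RK20449 libraries and 316, 263 and 467 of the Vehicle libraries, with a median of 2353 UMIs. Another, led by Ms4a7, Ccl12 and Fcrls, held 259, 302 and 844 against 1539, 1513 and 1715, with a median of 3727.5 UMIs. A cluster led by Cd74 and H2 genes, which had no class name in that clustering, held 82, 80 and 145 against 216, 452 and 818.

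Hck itself (ENSMUSG00000003283, chromosome 2, 153108468 to 153151441) fell in RK20449 macrophage-like cells, from 74.9 ± 7.52 CPM (SD, n = 3) to 40.6 ± 4.66 (SD, n = 3), a log2 change of -0.88 (SE 0.12, adjusted p = 0.000896). Src, the founding member of the family, fell as well (-1.02, SE 0.22, adjusted p = 0.0131), though not without Vehicle 1 (adjusted p = 0.0597) or without RK20449 2 (0.0545). Lyn (-0.39, adjusted p = 0.0545), Fgr (0.44, 0.0699) and Fyn (0.27, 0.107) did not pass.

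**Figure D1:**
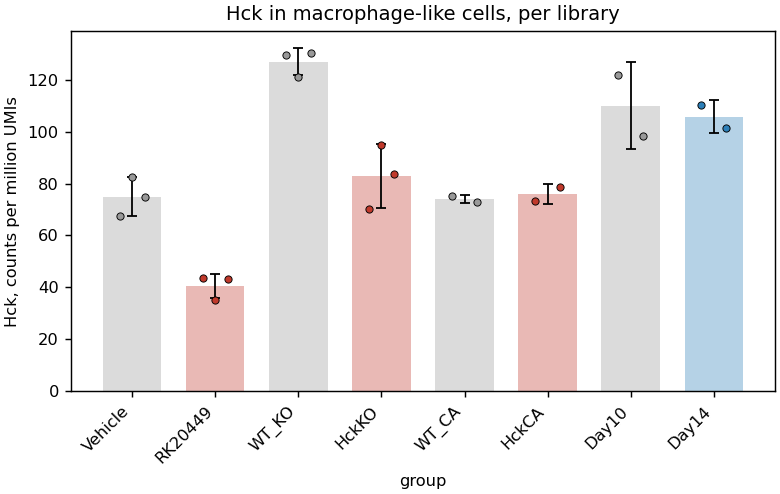
Hck RNA in macrophage-like cells, as CPM on the vertical axis, for each library by group on the horizontal axis; bars are group means and error bars the SD. RK20449 lay at 40.6 ± 4.66 against 74.9 ± 7.52 in Vehicle, HckKO at 82.9 ± 12.4 against 127 ± 5.05 in WT_KO, and HckCA at 76.1 ± 3.77 against 74.2 ± 1.48 in WT_CA.

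Of 34 lists tested in macrophage-like cells, 14 passed with camera's preset correlation and none with an estimated one; 9 passed when genes below 0.25 times their level in another class were left out. Of 20 lipid-associated macrophage genes, 9 rose, 2 fell and 9 did not pass. Among these, 10 rose and 2 fell when adjusted over the list alone (camera adjusted p = 5.81e-09; adjusted p = 0.184 with an estimated correlation). Apoc1, an apolipoprotein (2.72), and Abca1, a cholesterol exporter (0.80), were among the rises. Of 16 MHC class I presentation genes, 8 fell and 8 did not pass. Among these, 13 fell when adjusted over the list alone (adjusted p = 1.79e-09; adjusted p = 0.278 with an estimated correlation). They included Psmb9 and Psmb8, subunits of the immunoproteasome (-0.91 and -0.81), and H2-D1 (-0.56). Of 17 interferon gamma response genes, 7 fell and 10 did not pass. Among these, 8 fell when adjusted over the list alone (adjusted p = 3.88e-08; adjusted p = 0.184 with an estimated correlation). Examples were Gbp7 (-1.03), Cxcl10, a T cell chemoattractant (-1.12), and Irf8 (-0.58). Of 15 pro-inflammatory macrophage genes, 4 fell and 11 did not pass. Among these, 8 fell when adjusted over the list alone (adjusted p = 2.61e-06; adjusted p = 0.184 with an estimated correlation). They included Nfkbia, an NF-kappaB inhibitor and target (-0.78), and Tnf (-0.58), and this list did not pass when genes below 0.25 times their level in another class were left out. Of 9 MHC class II genes, 3 fell and 6 did not pass. Among these, 6 fell when adjusted over the list alone (adjusted p = 5.12e-06; adjusted p = 0.285 with an estimated correlation). Examples were H2-DMa (-0.88) and H2-DMb1 (-0.60).

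Markers of other cells and of RNA quality moved in the same class. Of 11 collagens, 5 rose and 6 did not pass. Among these, 7 rose when adjusted over the list alone (adjusted p = 3.64e-05; adjusted p = 0.184 with an estimated correlation). Col3a1 (1.04) and Col1a1 (1.50) are genes of fibroblasts and other mesenchymal cells. Of 13 mitochondrially encoded genes, 9 rose and 4 did not pass. Among these, 13 rose when adjusted over the list alone (adjusted p = 1.86e-11; adjusted p = 0.233 with an estimated correlation). Examples were mt-Nd2 (0.67) and mt-Nd1 (0.55). Of 20 dissociation and immediate early genes, 10 fell and 10 did not pass. Among these, 11 fell when adjusted over the list alone (adjusted p = 1.79e-09; adjusted p = 0.184 with an estimated correlation). Examples were Btg2 (-1.02), Jun (-0.85) and Fos (-0.51). Of 10 macrophage markers, 5 fell and 5 did not pass. Among these, 5 fell when adjusted over the list alone (adjusted p = 0.000441; adjusted p = 0.221 with an estimated correlation). Examples were Fcgr1 (-0.77) and Ms4a7 (-0.63).

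In T cell-like cells, 34 of 5973 genes passed (19 up, 15 down), or 118 without the filter on low counts. Abcg1 rose by 1.96 (adjusted p = 0.00087, from 24.3 ± 13.8 to 85.5 ± 18.8 CPM, SD, n = 3 each, edgeR), Scd2 by 2.20 and Khdc1a by 3.76. Nt5e, which makes adenosine from AMP, fell by 1.27, and Nrgn fell by 1.27, though not with DESeq2. Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705), an inhibitory receptor of activated T cells, was at 13.0 ± 8.73 CPM (SD, n = 3) against 73.5 ± 29.4 (SD, n = 3), a log2 change of -2.37 (SE 0.41, adjusted p = 0.00865, edgeR). It did not pass without Vehicle 2 (adjusted p = 0.0908) or without RK20449 1 (0.0836). Of 12 inhibitory receptor genes, 2 fell and 10 did not pass. Among these, 4 fell when adjusted over the list alone (adjusted p = 1.66e-06; adjusted p = 0.263 with an estimated correlation). Cd160, the other gene of that list to fall, changed by -1.22 and did not pass without Vehicle 2 (adjusted p = 0.0583). Of 5 macrophage markers, 0 passed in edgeR over all genes and 2 fell when adjusted over the list alone (adjusted p = 0.00245; adjusted p = 0.406 with an estimated correlation). That list did not pass without Vehicle 3 (0.0538) or RK20449 1 (0.0583). The make-up of the class differed: a cluster led by Dapl1 and Ccr7 held 46, 104 and 17 of 293, 343 and 144 RK20449 cells. It held 18, 22 and 29 of 342, 462 and 886 Vehicle cells. One with Lag3 as a leading gene held 101, 41 and 6 against 33, 41 and 180. Changes within clusters were not tested.

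Tumour or mesenchymal-like cells of RK20449 and Vehicle lay largely in separate clusters. A cluster of 10980 cells, led by Mast4, Brinp3 and Mgp, held 3994, 2927 and 2824 cells of the RK20449 libraries and 459, 368 and 377 of the Vehicle libraries. Another, of 7312 cells, held 2391, 2415 and 1860 of Vehicle and 130, 235 and 262 of RK20449. Of the 2009 genes, 1170 rose and 839 fell. The count was 936 without Vehicle 1, 731 without Vehicle 2 and 617 without RK20449 3. Lgals7 (chromosome 7, 28863853 to 28866284) was at 125.8 ± 12.8 CPM (SD, n = 3) against 36.1 ± 2.19 (SD, n = 3), a log2 change of 1.80 (SE 0.10, adjusted p = 2.66e-05, edgeR). The other rises by the rule were Mt2, a metallothionein (1.73), Sulf2, a heparan sulfatase (1.58), Ly6a (1.46) and Pdzrn3 (1.43). The falls were Itpkc (-1.60), Klf2 (-1.56), Dnajb1, a heat shock co-chaperone (-1.55), Dusp5, a phosphatase of ERK (-1.42), and Hmgcs1, an enzyme of cholesterol synthesis (-1.35). Of 20 dissociation and immediate early genes, 17 fell and 3 did not pass. Among these, 18 fell when adjusted over the list alone (camera adjusted p = 2.4e-26; adjusted p = 0.316 with an estimated correlation). Examples were Egr1 (-1.18) and Ier2 (-0.96). Of 7 fibroblast markers, 4 rose and 3 did not pass. Among these, 4 rose when adjusted over the list alone (adjusted p = 5.61e-05; adjusted p = 0.423 with an estimated correlation). Examples were Dcn (1.55) and Pdgfra (0.91). Of 13 collagens, 6 rose, 1 fell and 6 did not pass. Among these, 7 rose and 1 fell when adjusted over the list alone (adjusted p = 2.3e-05; adjusted p = 0.423 with an estimated correlation). Col3a1 (0.82) and Col1a1 (1.02) were among them. The collagen result turned direction when genes below 0.25 times their level in another class were left out (adjusted p = 0.5).

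The lower share of mature dendritic cell-like cells (log2 change -1.68, SE 0.39, adjusted p = 0.0455, edgeR) had an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. It did not pass without Vehicle 1, 2 or 3 or RK20449 1 or 3 (adjusted p = 0.0805 to 0.167), or with the replicate number as a block (-1.72, adjusted p = 0.113). T cell-like cells made up 2.87% ± 1.34 (SD, n = 3) of RK20449 and 6.46% ± 2.98 (SD, n = 3) of Vehicle cells, with no overlap between libraries, and did not pass (log2 -1.17, adjusted p = 0.133, exact permutation p = 0.1). Neutrophil-like cells, whose median of 703 UMIs in these libraries lies near the minimum of 500 per cell, made up 2.72% ± 1.35 and 0.900% ± 0.579 and did not pass (log2 1.59, adjusted p = 0.133). They passed with the replicate number as a block (log2 1.73, adjusted p = 0.0329) and with stricter cells (log2 3.79, adjusted p = 0.0472). Macrophage-like cells made up 28.1% ± 7.31 and 25.1% ± 1.21 (adjusted p = 0.615).

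**Figure D2:**
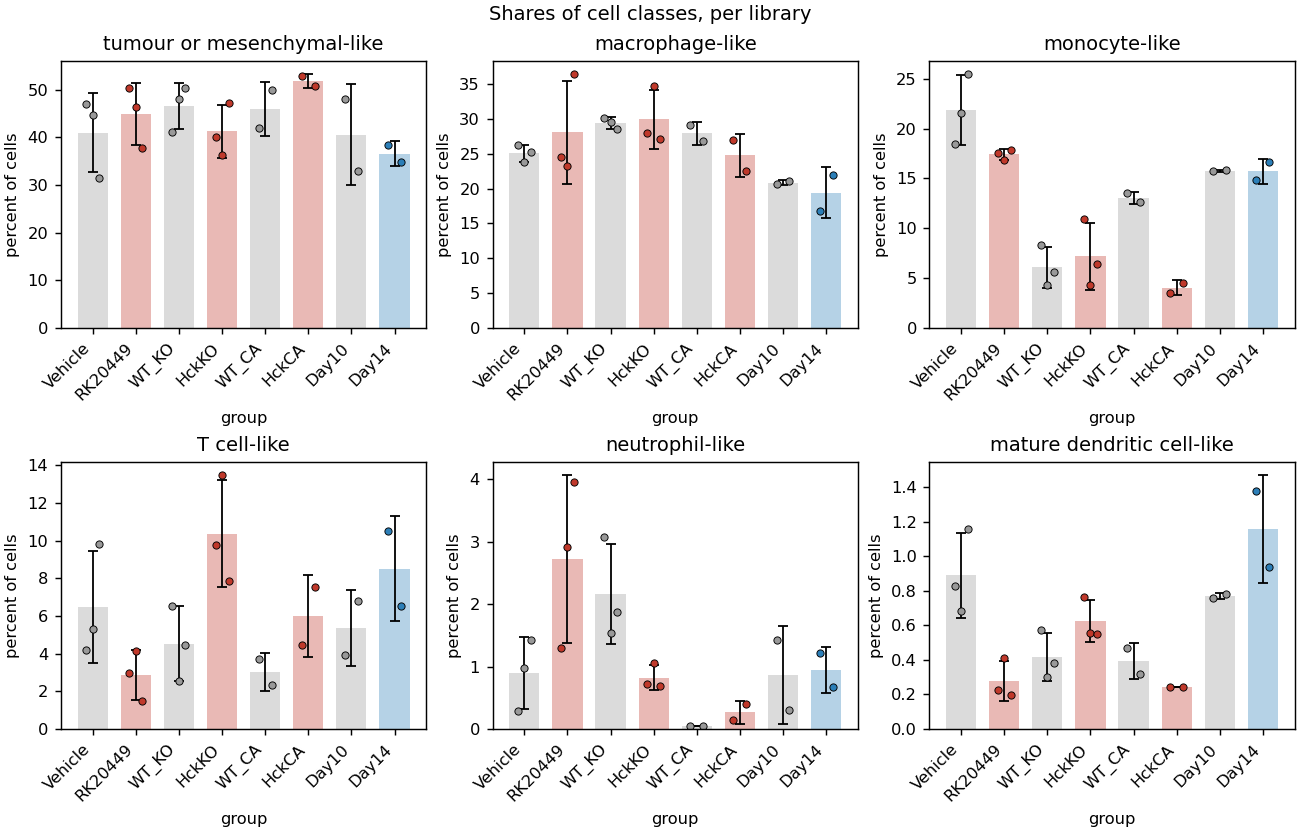
Percent of the cells of each library (vertical axis) in 6 cell classes, by group (horizontal axis), with points for libraries, bars for means and error bars for the SD. T cell-like cells averaged 2.87% in RK20449 against 6.46% in Vehicle and 10.4% in HckKO against 4.52% in WT_KO, and monocyte-like cells 4.03% in HckCA against 13.1% in WT_CA.

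The HckKO and WT_KO libraries addressed what loss of Hck in the mouse changed in the tumour. Hck RNA was lower in HckKO macrophage-like cells, at 82.9 ± 12.4 CPM (SD, n = 3) against 127 ± 5.05 (SD, n = 3), but it was not absent. The largest rise by the rule was in Pianp (log2 6.06), which had 2 other called genes within 1 Mb, C1rb (6.59) and Eno2 (4.12), named after their values were seen. Pde4d, a cyclic AMP phosphodiesterase, was 11.2-fold higher; a passenger variant at either gene was not excluded. Of 23 genes of hypoxia and glycolysis 9 fell, among them Slc2a1, the glucose transporter GLUT1, and Egln3, a prolyl hydroxylase induced by hypoxia. The list passed with the preset correlation only (adjusted p = 0.390 with an estimated correlation). In all, 173 of 12823 genes passed in macrophage-like cells (56 up, 117 down). In share of cells 0 classes passed in edgeR, where 3 had an unadjusted p under 0.05 and 2 passed with TMM factors.

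The fall in Hck in macrophage-like cells was -0.62 on the log2 scale (SE 0.11, adjusted p = 0.0328, edgeR). It did not pass without WT_KO 1, WT_KO 2, WT_KO 3 or HckKO 3, with values of -0.60, -0.65, -0.59 and -0.62, or with the replicate number as a block (-0.63). In T cell-like cells Hck was higher in HckKO, with 114 UMIs against 2 (20.8 ± 6.80 CPM against 0.510 ± 0.884, SD, n = 3 each), a ratio of 24.7 with a 95% exact counting interval of 6.68 to 206. That difference (adjusted p = 0.00662, edgeR) did not pass without WT_KO 2 (0.0910) or without WT_KO 3 (0.0764). The labels do not say which part of the gene was altered, and a 3′ tag outside that part would still be counted.

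Pianp (ENSMUSG00000030329, chromosome 6, 124996694 to 125003096) was at 51.3 ± 12.2 CPM (SD, n = 3) in HckKO and 0.747 ± 0.392 (SD, n = 3) in WT_KO (SE of log2 0.33, adjusted p = 0.00038, edgeR). Pde4d (ENSMUSG00000021699, chromosome 13, 108449948 to 109953461) was at 1062 ± 101 against 94.95 ± 7.14 CPM, a log2 change of 3.48 (SE 0.12, adjusted p = 1.76e-06). Ankrd37, a target of hypoxia-inducible factor (ENSMUSG00000050914, chromosome 8, 45996902 to 46005707), was at 14.7 ± 2.75 against 49.7 ± 3.50 CPM, a log2 change of -1.77 (SE 0.14, adjusted p = 0.000351). Slc2a1 (ENSMUSG00000028645, chromosome 4, 119108711 to 119137983) was at 44.2 ± 4.51 against 110 ± 17.4 CPM, a log2 change of -1.32 (SE 0.13, adjusted p = 0.0014). The other rises by the rule were Plxnd1, a semaphorin receptor (2.09), Wdfy1 (1.11), Ncf4, a subunit of the phagocyte NADPH oxidase (0.99), Klf4 (0.97), Mtmr10 (0.95) and Ankrd28 (0.87). The other falls were Serinc3 (-1.68), Apobec3, a cytidine deaminase that restricts retroviruses (-1.62), Sulf2 (-1.38), Ly86 (-1.14) and the heat shock genes Hspa1b (-1.85) and Hspa1a (-1.35), whose copies are nearly alike. Klf4 (adjusted p = 0.0693) and Mtmr10 (0.0600) did not pass without WT_KO 2. Hspa1a did not pass with one start of the clustering. Without WT_KO 1, 2 or 3 or HckKO 3, adjusted p was 0.0740 to 0.158 for Ankrd28, 0.0609 to 0.121 for Hspa1b and 0.0990 to 0.142 for Ly86. None of the SRC family kinases other than Hck passed.

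**Figure D3:**
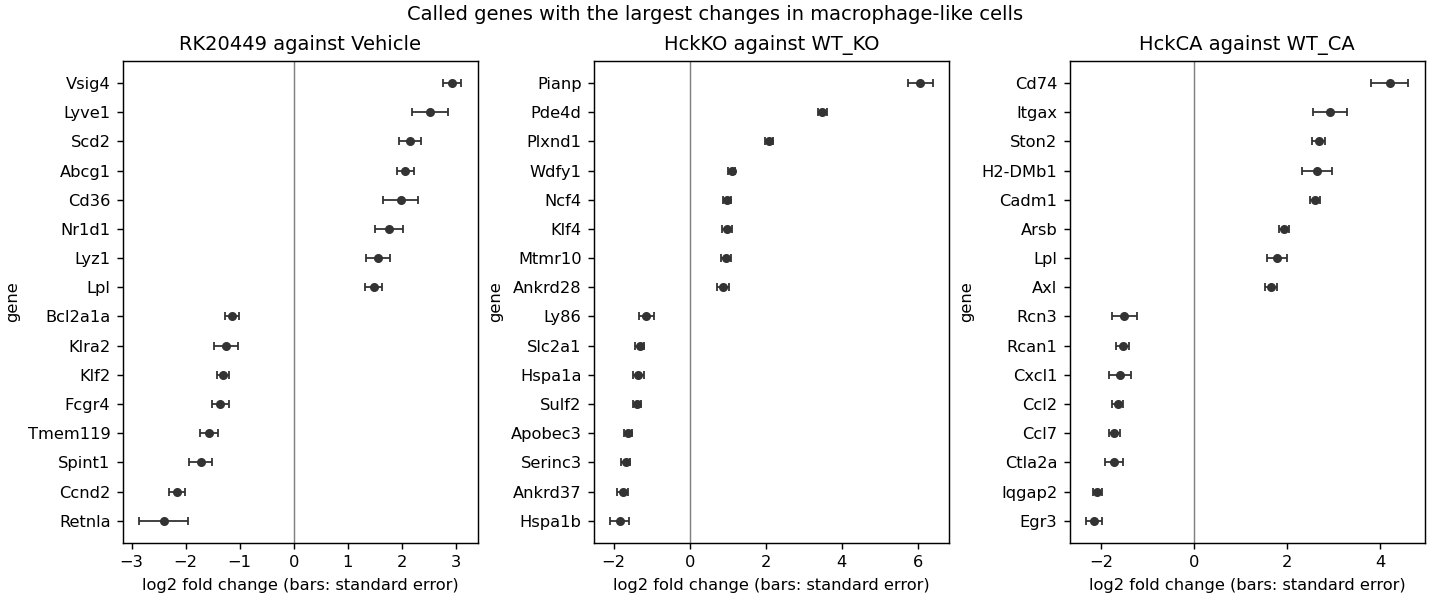
Log2 fold change (horizontal axis, with the SE as error bars) of the genes with the largest rises and falls by the rule in macrophage-like cells (vertical axis; members named for their list alone are not drawn) for RK20449 against Vehicle, HckKO against WT_KO and HckCA against WT_CA. Of the genes drawn, Pianp at 6.06 in HckKO and Cd74 at 4.20 in HckCA are the highest, and Retnla at -2.41 in RK20449 is the lowest.

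Of the 173 genes, 17 lay within 20 Mb of Hck on chromosome 2, or 9.83% against 1.91% of the genes tested, a ratio of 5.14 (Fisher's exact test, adjusted p = 5.49e-07); Serinc3 and Sulf2 are among them. HckKO 3 and WT_KO 3 stood apart from the other libraries of their groups: a chi-square per gene, from counts summed over all cells, was 139 to 162 for pairs with either of them and 25.2 to 69.0 for the other pairs. Without both libraries numbered 3, chosen after seeing the data, 5 genes passed. The count of 173 became 63 without WT_KO 1, 50 without WT_KO 2, 52 without WT_KO 3, 275 without HckKO 2 and 67 without HckKO 3. With other settings it was 323 with DESeq2, 385 without the filter on low counts and 84 with cells thinned to 2000 UMIs.

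**Figure D4:**
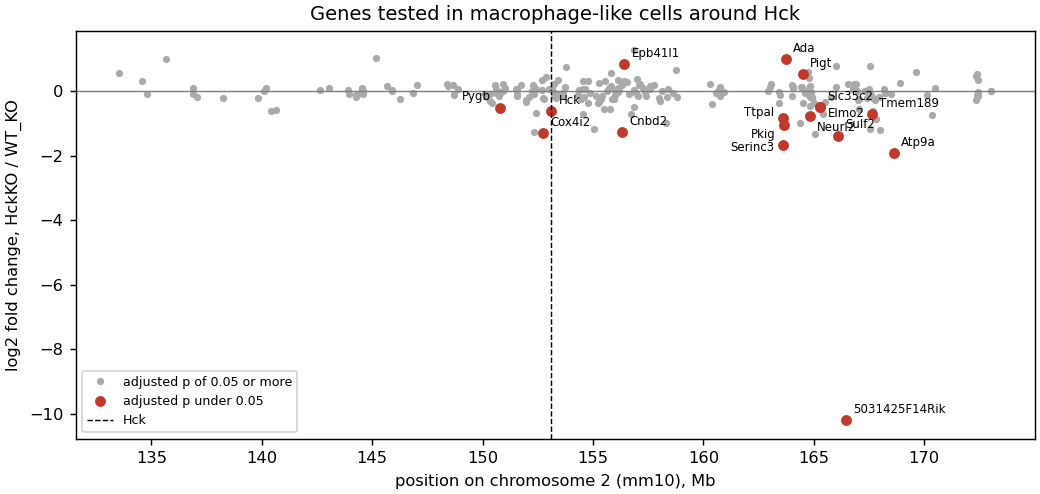
Log2 fold change of each gene tested in HckKO against WT_KO macrophage-like cells (vertical axis) by its position on chromosome 2 (horizontal axis, Mb) within 20 Mb of Hck; red points are genes that passed. The red points number 17 and include Hck at -0.62, Serinc3 at -1.68 and Sulf2 at -1.38.

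Of 35 lists tested in macrophage-like cells 6 passed, none of them with an estimated correlation; 15 passed without HckKO 1 and 12 at Leiden resolution 0.5. Of 23 hypoxia and glycolysis genes, 9 fell and 14 did not pass. Among these, 15 fell when adjusted over the list alone (camera adjusted p = 2.68e-37; adjusted p = 0.390 with an estimated correlation), with Egln3 (-2.49) and Adm, adrenomedullin (-2.51), beside Ankrd37 and Slc2a1. Of 20 dissociation and immediate early genes in the same cells, 3 rose, 3 fell and 14 did not pass, or 5 rose and 4 fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.939). Dusp1 rose by 0.82, though not without WT_KO 2 (adjusted p = 0.186), WT_KO 3 (0.142) or HckKO 3 (0.115) or with the replicate number as a block (0.144), and the heat shock genes above fell. Of 26 proliferation genes, 3 rose and 23 did not pass. Among these, 16 rose when adjusted over the list alone (adjusted p = 9.07e-18; adjusted p = 0.497 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 0.82, though not at Leiden resolution 0.5 or with one start of the clustering. Of 20 lipid-associated macrophage genes, 0 passed in edgeR, over all genes or adjusted over the list alone, and camera put the list lower in HckKO (adjusted p = 0.00348; adjusted p = 0.906 with an estimated correlation). The same tests put 19 NF-kappaB target genes higher (adjusted p = 0.00348; adjusted p = 0.906 with an estimated correlation), with 0 passing in edgeR, over all genes or adjusted over the list alone; that list did not pass without WT_KO 2 (0.0652) or HckKO 2 (0.0716). Of 22 epithelial to mesenchymal genes, 2 rose and 20 did not pass. Among these, 4 rose and 1 fell when adjusted over the list alone (adjusted p = 0.00348; adjusted p = 0.497 with an estimated correlation), and the list did not pass without HckKO 3 (0.0735). Of 10 T cell activation and signalling genes, 3 rose, 1 fell and 6 did not pass. Among these, 4 rose and 1 fell when adjusted over the list alone (adjusted p = 0.00525; adjusted p = 0.497 with an estimated correlation). It did not pass without WT_KO 2 or 3 or HckKO 2 or 3 (0.0512 to 0.300). Both of these lists hold Cd44, a hyaluronan receptor, which rose by 0.71, though not without WT_KO 2 (0.0697). Macrophage-like cells of HckKO 1 held 617 cells of the F13a1 and Pf4 cluster and 83 of the cluster led by Cd74 and H2 genes, against 147 and 979 in HckKO 2, 321 and 401 in HckKO 3, and 157 to 374 and 505 to 711 in WT_KO.

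In T cell-like cells 20 of 8961 genes passed (5 up, 15 down). Pde4d was at 2645 ± 428 CPM (SD, n = 3) against 119 ± 8.49 (SD, n = 3), a log2 change of 4.47 (SE 0.20, adjusted p = 5.51e-08, edgeR). Apobec3 was at 25.8 ± 7.66 against 174 ± 11.6 CPM, a log2 change of -2.72. Klra1 (-1.91) and Klrb1c (-2.77), receptors of NK cells, also fell. The make-up of the class differed: the NK subset was 7.02% ± 1.99 of T cell-like cells in HckKO and 25.2% ± 10.3 in WT_KO (SD, n = 3 each; adjusted p = 0.0261, edgeR), and of all cells 0.768% ± 0.426 and 1.02% ± 0.319 (adjusted p = 0.520, edgeR). The former did not pass without WT_KO 2 or 3 or HckKO 1, 2 or 3 (0.0576 to 0.122). Klra1 did not pass without WT_KO 2 (adjusted p = 0.0819) or WT_KO 3 (0.0579), or with stricter cells. Klrb1c did not pass without WT_KO 2 or 3 or HckKO 1, 2 or 3 (0.0859 to 0.311). Of 12 naive and memory T cell genes, 0 passed in edgeR, over all genes or adjusted over the list alone. The camera test gave an adjusted p of 3.12e-09, higher in HckKO (adjusted p = 0.593 with an estimated correlation). Klf2 was at 1.76 (adjusted p = 0.424) and passed with the replicate number as a block (1.78, adjusted p = 3.32e-06). Naive-like cells were 47.3% ± 22.6 of T cell-like cells in HckKO and 15.4% ± 15.8 in WT_KO (SD, n = 3 each; adjusted p = 0.231, edgeR). Of 5 macrophage markers, 0 passed in edgeR, over all genes or adjusted over the list alone, and camera put the list higher in HckKO (adjusted p = 0.0336; adjusted p = 0.593 with an estimated correlation). It did not pass without WT_KO 3 (0.136) or HckKO 3 (0.291). The count of 20 genes became 4 without WT_KO 2, 5 without WT_KO 3, 51 without HckKO 1, 82 without HckKO 2 and 12 without HckKO 3. With the replicate number as a block it was 301 (192 up, 109 down), in a class where same-numbered libraries deviated together. The count was 3 without both libraries numbered 3, 31 with DESeq2, 208 without the filter on low counts and 12 when genes below 0.25 times their level in another class were left out.

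In tumour or mesenchymal-like cells 7 of 15235 genes passed (3 up, 4 down). Egln3 (ENSMUSG00000035105, chromosome 12, 54178981 to 54203860) was at 14.0 ± 0.0847 CPM (SD, n = 3) against 27.5 ± 2.01 (SD, n = 3), a log2 change of -0.97 (SE 0.08, adjusted p = 0.0266, edgeR). It lost its call without WT_KO 2 (0.0629) or HckKO 2 (0.174). Of 23 hypoxia and glycolysis genes, 2 fell and 21 did not pass. Among these, 17 fell when adjusted over the list alone (camera adjusted p = 3.21e-37; adjusted p = 0.0697 with an estimated correlation). Of 19 dissociation and immediate early genes, 1 rose and 18 did not pass. Among these, 15 rose and 1 fell when adjusted over the list alone (adjusted p = 7.74e-28; adjusted p = 0.0697 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, rose by 0.96, though not without WT_KO 1, 2 or 3 or HckKO 2 (adjusted p = 0.0544 to 0.216). The count of 7 genes became 3 without WT_KO 1, 0 without WT_KO 2, 42 without HckKO 1, 0 without HckKO 2 and 66 without HckKO 3. It was 279 with DESeq2, 616 with the replicate number as a block, 120 without the filter on low counts and 17 without both libraries numbered 3.

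Among the cell classes, T cell-like cells made up 10.4% ± 2.88 (SD, n = 3) of HckKO and 4.52% ± 2.00 (SD, n = 3) of WT_KO cells (log2 1.20, SE 0.40, adjusted p = 0.0841, edgeR; exact two-sided permutation p = 0.1) and passed without WT_KO 1 (0.0360). Neutrophil-like cells, with a median of 2471 UMIs in these libraries, made up 0.822% ± 0.202 and 2.16% ± 0.804 (log2 -1.39, adjusted p = 0.0541) and passed without WT_KO 2 (0.0404). Both classes passed with TMM factors on the class counts (0.0218). Macrophage-like cells made up 30.0% ± 4.16 and 29.4% ± 0.858 (adjusted p = 0.907).

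The HckCA and WT_CA libraries addressed what a constitutively active Hck changed. Macrophage-like cells of HckCA tumours held 18.4-fold more RNA of Cd74, the invariant chain of MHC class II, and 3.14-fold more of Axl, a receptor kinase for apoptotic cells (n = 2 each). They held less of the monocyte chemoattractants Ccl2 and Ccl7 and of Egr3. Of 12581 genes 1757 passed (936 up, 821 down), with 6 of 10 MHC class II, 11 of 16 MHC class I and 8 of 20 lipid-associated genes rising, and 10 of 26 chemokines and receptors falling and 3 rising. These 4 lists passed with the preset correlation only (adjusted p = 0.558 each with an estimated correlation). Monocyte-like cells were 4.03% ± 0.731 (SD, n = 2) of HckCA and 13.1% ± 0.662 (SD, n = 2) of WT_CA cells, a class nearly absent with one start of the clustering.

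Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652) was at 7547 ± 3129 CPM (SD, n = 2) in HckCA and 411 ± 18.9 (SD, n = 2) in WT_CA macrophage-like cells, a log2 change of 4.20 (SE 0.40, adjusted p = 0.0175, edgeR). Axl (ENSMUSG00000002602, chromosome 7, 25757273 to 25788705) was at 132 ± 23.8 against 42.0 ± 4.05 CPM, a log2 change of 1.65 (adjusted p = 1.19e-05). Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453) was at 633 ± 106 against 1978 ± 79.0 CPM, a log2 change of -1.64 (SE 0.12, adjusted p = 6.29e-08). The other rises by the rule were Ston2 (2.67), Cadm1, an adhesion molecule (2.59), Arsb, a lysosomal sulfatase (1.93), Itgax, the integrin CD11c (2.92), H2-DMb1 (2.63) and Lpl (1.77). The other falls were Egr3 (-2.16), Iqgap2 (-2.09), Ctla2a (-1.74), Ccl7 (-1.72), Rcan1, a calcineurin regulator (-1.54), Cxcl1, a neutrophil chemoattractant (-1.60), and Rcn3 (-1.51). Without WT_CA 1 and without WT_CA 2, in that order, the adjusted p was 0.186 and 0.224 for Cd74, 0.149 and 0.190 for Itgax, 0.215 and 0.256 for H2-DMb1. In the same order it was 0.130 and 0.134 for Lpl, 0.0629 and 0.0962 for Cxcl1, and 0.193 and 0.202 for Rcn3. Hck itself was at 76.1 ± 3.77 CPM (SD, n = 2) against 74.2 ± 1.48 (SD, n = 2), a log2 change of 0.04 (SE 0.08, adjusted p = 0.831). It was at -0.23 at Leiden resolution 0.5 and -0.12 with one start of the clustering. The kinases Fgr (1.15, adjusted p = 0.0072) and Src (1.23, 0.0220) rose, though not without WT_CA 1 (0.154 and 0.220) or WT_CA 2 (0.207 and 0.265).

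Of 33 lists tested in macrophage-like cells 15 passed, none of them with an estimated correlation. Of 10 MHC class II genes, 6 rose and 4 did not pass. Among these, 10 rose when adjusted over the list alone (camera adjusted p = 6.34e-20; adjusted p = 0.558 with an estimated correlation). H2-DMa (1.38) and H2-DMb2 (1.49) were among them and were at -0.04 and -0.17 at Leiden resolution 0.5. Of 16 MHC class I genes, 11 rose and 5 did not pass. Among these, 14 rose when adjusted over the list alone (adjusted p = 8.92e-09; adjusted p = 0.558 with an estimated correlation). Examples were H2-Q6 (1.96), H2-D1 (0.67) and B2m (0.61). Of 20 lipid-associated macrophage genes, 8 rose and 12 did not pass. Among these, 9 rose when adjusted over the list alone (adjusted p = 1.16e-08; adjusted p = 0.558 with an estimated correlation). Examples were Abcg1 (0.91), Lgals3 (0.95) and Lipa (0.70). Of 26 chemokines and receptors, 3 rose, 10 fell and 13 did not pass. Among these, 3 rose and 11 fell when adjusted over the list alone (adjusted p = 9.86e-10; adjusted p = 0.558 with an estimated correlation). Examples were Ccl4 (-1.50), Ccl3 (-1.09) and Cxcl2 (-1.22). Of 18 alternatively activated macrophage genes, 5 rose, 9 fell and 4 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.000104; adjusted p = 0.558 with an estimated correlation). Examples were Ccl24 (-1.89), Il10 (-1.85) and Mrc1, the mannose receptor (-0.82). Of 23 hypoxia and glycolysis genes, 7 rose and 16 did not pass. Among these, 11 rose when adjusted over the list alone (adjusted p = 0.000115; adjusted p = 0.596 with an estimated correlation), Slc2a1 (0.92) among them; this list did not pass with macrophage-like and monocyte-like cells pooled. Of 26 proliferation genes, 8 fell and 18 did not pass. Among these, 10 fell when adjusted over the list alone (adjusted p = 0.000222; adjusted p = 0.558 with an estimated correlation), Mcm3 (-0.59) among them, and the list turned direction with one start of the clustering (adjusted p = 0.0454).

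The make-up of the macrophage-like class differed between these groups. A cluster led by Cd74 and H2 genes held 409 and 725 cells in the HckCA libraries and 90 and 84 in WT_CA. A cluster led by F13a1 and Pf4 held 380 and 138 against 1075 and 1489. Median UMIs per cell were 18678.5 to 18740 in HckCA and 9882 to 11855.5 in WT_CA libraries. With macrophage-like and monocyte-like cells pooled, an alternative added after the first results were seen, Cd74 was at 1.60 (SE 0.33, adjusted p = 0.0760). The count of 1757 genes became 657 without WT_CA 1 and 568 without WT_CA 2, and was 519 with one start of the clustering, 914 with DESeq2 and 753 with cells thinned to 2000 UMIs.

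In T cell-like cells 20 of 6591 genes passed (11 up, 9 down). Penk, proenkephalin, rose by 3.63 (adjusted p = 0.00565, edgeR) and Klrc1, an inhibitory NK receptor, by 1.47 (adjusted p = 0.00506). Cxcl10 fell by 2.29 (adjusted p = 0.0125). These 3 genes did not pass with DESeq2. Xcl1, a chemokine for cross-presenting dendritic cells, fell by 1.09 (adjusted p = 0.00372), though not without HckCA 1 (0.156). Of 10 regulatory T cell genes, 0 passed in edgeR over all genes and 5 rose when adjusted over the list alone (camera adjusted p = 1.06e-05; adjusted p = 0.626 with an estimated correlation). Of 6 MHC class II genes, 2 rose and 4 did not pass. Among these, 3 rose when adjusted over the list alone (adjusted p = 4.53e-05; adjusted p = 0.626 with an estimated correlation). Cd74 (1.32) was among them and did not pass without HckCA 1 (0.281). It was at 96.5 CPM against 37.5, and at 7547 against 411 in macrophage-like cells of the same libraries, so that free RNA would move it the same way; C1qa, a macrophage gene, was at 31.7 against 27.3 in T cell-like cells. The count of 20 genes became 118 without WT_CA 1 and 73 without WT_CA 2, and was 4 with DESeq2, 12 with stricter cells, 46 with the replicate block and 54 without the filter on low counts.

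In tumour or mesenchymal-like cells 1134 of 15451 genes passed (618 up, 516 down). Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039), was at 33.7 CPM against 131, a log2 change of -1.96 (SE 0.12, adjusted p = 8.63e-07, edgeR). The other falls by the rule were Rrad (-1.68), Btg2 (-1.66), Cxcl10 (-1.32) and Cxcl1 (-1.27). The rises were Mt2 and Mt1, metallothioneins (1.57 and 1.13), Enpp2, autotaxin (1.27), Id4 (1.13) and Polg2 (1.08). Of 8 MHC class II genes, 6 rose and 2 did not pass. Among these, 7 rose when adjusted over the list alone (camera adjusted p = 3.88e-21; adjusted p = 0.344 with an estimated correlation). Examples were Cd74 (1.80) and H2-Aa (1.94). Cd74 was at 17.3 CPM against 5.02, and at 7547 against 411 in macrophage-like cells of the same libraries, so that free RNA would move it the same way; C1qa, a macrophage gene, was at 6.98 against 6.83 here. Of 19 NF-kappaB target genes, 10 fell and 9 did not pass. Among these, 12 fell and 1 rose when adjusted over the list alone (adjusted p = 7.31e-15; adjusted p = 0.395 with an estimated correlation). Examples were Tnfaip3 (-0.89) and Cxcl2 (-1.80). Of 15 unfolded protein response genes, 1 rose, 7 fell and 7 did not pass. Among these, 1 rose and 8 fell when adjusted over the list alone (adjusted p = 1.22e-07; adjusted p = 0.395 with an estimated correlation). Examples were Creld2 (-1.11) and Hspa5, the chaperone BiP (-0.96). Of 18 dissociation and immediate early genes, 1 rose, 6 fell and 11 did not pass. Among these, 1 rose and 7 fell when adjusted over the list alone (adjusted p = 2.08e-15; adjusted p = 0.395 with an estimated correlation). The count of 1134 genes became 649 without WT_CA 1, 398 without WT_CA 2 and 3244 without HckCA 1, and was 1901 without the filter on low counts.

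The lower share of monocyte-like cells (log2 -1.69, SE 0.38, adjusted p = 0.00408, edgeR) did not pass without WT_CA 1 (adjusted p = 0.256), WT_CA 2 (0.229), HckCA 1 (0.0662) or HckCA 2 (0.199). B cell-like cells rose from 0.948% ± 0.751 to 2.94% ± 1.47 (SD, n = 2 each; adjusted p = 0.0241). Neutrophil-like cells rose from 0.0476% to 0.266% ± 0.181 (adjusted p = 0.0163), from 22 cells in all. B cell-like cells did not pass without WT_CA 1 (0.375), WT_CA 2 (0.487), HckCA 1 (0.277) or HckCA 2 (0.615). Neutrophil-like cells did not without WT_CA 1 (0.376), WT_CA 2 (0.426) or HckCA 1 (0.0552). No class passed at Leiden resolution 0.5 or with the replicate number as a block, B cell-like cells did not with doublets kept (0.0740), and with the experiment clustered alone only monocyte-like cells passed. With one start of the clustering, 1 and 0 cells of HckCA and 3 and 4 of WT_CA were monocyte-like, too few to test, and unnamed cells went from 264, 289, 381 and 407 to 642, 922, 899 and 1115 in HckCA 1, HckCA 2, WT_CA 1 and WT_CA 2. The share also depends on where the boundary with macrophage-like cells lies, which moved Cd74 when the 2 classes were pooled. An exact permutation test of 2 libraries against 2 cannot reach 0.05.

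Genes called in HckKO macrophage-like cells were compared with the change in HckCA. Of the 112 genes that fell in HckKO and were tested in HckCA, 92 had a higher and 20 a lower estimate there, with a median of 0.34 (camera adjusted p = 4.51e-11; adjusted p = 0.424 with an estimated correlation). Of them 43 rose in HckCA, where 8.33 would be expected from all genes tested (Fisher's exact test, p = 1.58e-20), and 4 fell, where 7.31 would be. Fisher's test counts genes as independent, so its p here and below does not measure variation between mice. The fry adjusted p was 0.0881 for this set and 0.172 for the rises in HckKO. Of the 49 tested genes that rose in HckKO, 18 had a higher and 31 a lower estimate in HckCA (camera adjusted p = 0.000458, or 0.424 with an estimated correlation). Of these, 17 fell in HckCA (3.20 expected, Fisher's exact test, p = 5.36e-09) and 6 rose (3.65). Slc2a1 (-1.32 in HckKO, 0.92 in HckCA) is an example. The RK20449 sets did not pass in HckKO (camera adjusted p = 0.0510, rises upward, and 0.498, falls downward). RK20449 falls opposed HckCA too, with 106 rising there (42.3 expected) and 51 falling (37.1). HckKO falls were also lower on day 14 (camera adjusted p = 0.0052).

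The Day14 and Day10 libraries addressed how untreated tumours differed between the days. Macrophage-like cells of day 14 tumours held less RNA of Ank2, a membrane adaptor (-1.43 on the log2 scale, n = 2 each), and of Plxdc2, a plexin domain receptor (-0.95), which were the only 2 of 12868 genes to pass in edgeR. In tumour or mesenchymal-like cells Hmox1, haem oxygenase, rose by 0.90 and Gas1 fell by 0.78, among 50 of 15573 genes (21 up, 29 down). In share of cells 0 classes passed in edgeR or with TMM factors, and 0 had an unadjusted p under 0.05, with T cell-like cells at 8.50% ± 2.77 (SD, n = 2) on day 14 and 5.35% ± 2.02 (SD, n = 2) on day 10. The lowest adjusted p of any class was 0.913.

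Ank2 (ENSMUSG00000032826, chromosome 3, 126921612 to 127499350) was at 22.8 ± 1.83 CPM (SD, n = 2) against 61.1 ± 3.27 (SD, n = 2; SE of log2 0.11, adjusted p = 0.0215, edgeR). Plxdc2 (ENSMUSG00000026748, chromosome 2, 16356304 to 16755839) was at 77.0 ± 3.45 against 149 ± 3.02 CPM (SE of log2 0.09, adjusted p = 0.0417). Without Day14 1 the adjusted p was 0.318 for Ank2 and 0.399 for Plxdc2, and without Day14 2 it was 0.317 and 0.3502. Neither passed with the replicate number as a block. In macrophage-like cells 1277 genes had an unadjusted p under 0.05 and 72 passed with DESeq2. The count of 2 became 20 without Day10 1, 304 without Day10 2, 0 without Day14 1 and 0 without Day14 2, and 504 without the filter on low counts. Hck was at 106 ± 6.41 against 110 ± 16.7 CPM (log2 -0.06, adjusted p = 0.907).

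Of 36 lists tested in macrophage-like cells 10 passed, with no member passing over all genes and no list passing with an estimated correlation; 22 passed without Day10 2 and 17 when genes below 0.25 times their level in another class were left out. Of 25 type I interferon response genes, 0 passed in edgeR over all genes and 6 rose when adjusted over the list alone (camera adjusted p = 4.31e-11; adjusted p = 0.631 with an estimated correlation), with Irf7 at 1.08 (adjusted p = 0.153 over all genes) as an example. Of 14 unfolded protein response genes, 7 rose when adjusted over the list alone (adjusted p = 2.08e-06; adjusted p = 0.631 with an estimated correlation), with Creld2 at 0.99 (0.0914 over all genes). Of 20 lipid-associated macrophage genes, 5 fell when adjusted over the list alone (adjusted p = 5.02e-10; adjusted p = 0.631 with an estimated correlation), with Apoe at -0.54 and Abca1 at -0.71. Of 26 proliferation genes, 0 passed in edgeR, over all genes or adjusted over the list alone. The camera adjusted p was 2.4e-12, higher on day 14 (adjusted p = 0.631 with an estimated correlation).

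In T cell-like cells 0 of 9131 genes passed in edgeR, where 410 had an unadjusted p under 0.05, and 1 passed with DESeq2. The count became 5 without Day10 1, 8 without Day10 2, 1 without Day14 1 and 24 without the filter on low counts. Ccl1, a chemokine of activated T cells, had 53 UMIs against 1 and did not pass (adjusted p = 0.386), with a ratio of 39.8 and an exact counting interval of 6.84 to 1600. Of 26 proliferation genes, 0 passed over all genes and 9 fell when adjusted over the list alone (camera adjusted p = 1.91e-14; adjusted p = 0.581 with an estimated correlation). Of 5 macrophage markers, 0 passed over all genes and 3 fell when adjusted over the list alone (adjusted p = 2.27e-08; adjusted p = 0.581 with an estimated correlation). That list did not pass without Day14 1 (0.124). Naive-like cells were 0.483% and 37.5% of T cell-like cells in Day10 1 and Day10 2, and 4.57% and 21.1% in Day14 1 and Day14 2.

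In tumour or mesenchymal-like cells Hmox1 (chromosome 8, 75093621 to 75100589) was at 170 ± 11.3 CPM (SD, n = 2) on day 14 and 91.1 ± 4.57 (SD, n = 2) on day 10 (SE of log2 0.07, adjusted p = 0.0193, edgeR). Cyp51, an enzyme of cholesterol synthesis, rose by 0.80, and Lif, a cytokine, and Spry1, an inhibitor of growth factor signalling, fell by 0.92 and 0.80. Of 25 type I interferon response genes, 0 passed in edgeR over all genes and 11 rose when adjusted over the list alone (camera adjusted p = 2.63e-08; adjusted p = 0.788 with an estimated correlation). Of 15 unfolded protein response genes, 2 rose and 13 did not pass. Among these, 9 rose when adjusted over the list alone (adjusted p = 2.63e-08; adjusted p = 0.953 with an estimated correlation). Herpud1 (0.46) and Xbp1 (0.49) were those that rose. Neither passed without Day10 2 (0.102 and 0.121). The count of 50 genes became 79 without Day10 1, 161 without Day14 1 and 414 without Day14 2. It was 482 with DESeq2, 457 with the replicate number as a block, 836 without the filter on low counts and 79 when genes below 0.25 times their level in another class were left out.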

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

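The comparison of share changes between experiments, and all tests of it, were chosen after the shares were seen; the relabelling of libraries and the test without tumour cells were set before their own results were seen.

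The change in the T cell-like share differed between the inhibitor and the knockout: T cell-like cells went from 6.46% ± 2.98 (SD, n = 3) in Vehicle to 2.87% ± 1.34 in RK20449, and from 4.52% ± 2.00 in WT_KO to 10.4% ± 2.88 in HckKO, a log2 difference between the changes of -2.37 (SE 0.68, adjusted p = 0.0166, edgeR interaction over 3 and 3 libraries in each experiment). Against few-UMI cells or tumour cell numbers as the whole cause, the difference was -2.533 with stricter cell filters (unadjusted p = 0.00416) and -2.051 with tumour cells left out of the total (0.00897). Lymph node tissue stays open. Leaving out naive-like T cells gave -1.868 (unadjusted p = 0.0317, 0.00552 with them). It took 0 or 1 cell from each v2 library, whose Dapl1 and Ccr7 cluster stayed. In HckKO naive-like cells were much of the rise, the rest being 5.67% ± 3.60 against 3.62% ± 0.973 in WT_KO (adjusted p = 0.394). Of 100 relabellings within the experiments, 1, the real one, gave a difference as large (2.37, highest other 2.353). The class was picked after the shares were seen, so chance stays open. Also open and untested is the difference in library chemistry. The inhibitor may also act on T or tumour cells through an SRC family kinase other than HCK, which was not tested.

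Other changes in share differed between these experiments by the same test. The log2 difference was -2.244 for mature dendritic cell-like cells (adjusted p = 0.0126). It was 2.985 for neutrophil-like cells (adjusted p = 0.0166), and 5.203 (SE 1.04, adjusted p = 0.00416) with stricter cells. For endothelial cell-like cells it was 1.439 (adjusted p = 0.0377). It did not pass at Leiden resolution 0.5 (0.0593) or without Vehicle 1, 2 or 3, RK20449 1 or 2, WT_KO 2 or 3, or HckKO 1 or 2 (0.0567 to 0.0888).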

How the results depend on the processing

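Alternatives named as added above were chosen after seeing the data. For named genes, 8878 of 9815 values under an alternative kept their direction and their side of the threshold, 481 no longer passed, 376 newly passed, 78 moved and 2 turned direction. For gene lists, 1837 of 2177 did so, 331 no longer passed and 9 turned direction, and for class shares 356 of 426 did so. With groups of 2, leaving out a library assumes that the lone sample varies like the other group. Replicate numbers paired the samples in some classes only. In macrophage-like, T cell-like, tumour or mesenchymal-like and monocyte-like cells, 4, 3, 5 and 3 of 6 RK20449 and Vehicle libraries and 3, 6, 4 and 4 of 6 HckKO and WT_KO libraries were closest to their own number. In HckCA and WT_CA tumour or mesenchymal-like cells same-numbered libraries deviated in opposite ways (r = -0.116 across genes), and with their numbers crossed as a block 4024 genes passed (1796 up, 2228 down); the cause was not tested. Depth limits neutrophil-like and T cell-like cells of the v2 libraries, with medians of 703 and 1619 UMIs. The cause was not tested for any value below except where fewer samples or other genes were tested.

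With no filter on low counts, which changes the genes tested, the genes that passed were 385, 208 and 120 for HckKO and 504, 24 and 836 for Day14 in macrophage-like, T cell-like and tumour or mesenchymal-like cells. They were 1779 and 118 for RK20449 in the first 2 classes and 54 and 1901 for HckCA in the last 2. With DESeq2, whose own filter also changes the genes tested, they were 323, 31 and 279 for HckKO in macrophage-like, T cell-like and tumour or mesenchymal-like cells, 914 and 4 for HckCA in macrophage-like and T cell-like cells, and 72, 1 and 482 for Day14 in the 3 classes; the cause was not tested. With the replicate number as a block they were 301 and 616 for HckKO in T cell-like and tumour or mesenchymal-like cells, 46 for HckCA in T cell-like cells, and 0 and 457 for Day14 in macrophage-like and tumour or mesenchymal-like cells, 0 classes passed in share for HckCA, and Hck was at -0.6272 in HckKO without passing; the cause was not tested. When genes below 0.25 times their level in another class were left out, 12 and 0 passed for HckKO in T cell-like and tumour or mesenchymal-like cells, 7 and 79 for Day14 in macrophage-like and tumour or mesenchymal-like cells, and 9 (RK20449) and 17 (Day14) gene lists. At Leiden resolution 0.5, 3 genes passed for HckKO in tumour or mesenchymal-like cells and 19 for Day14 in macrophage-like cells, 12 gene lists passed for HckKO, 0 classes in share for HckCA, and Hck was at -0.2268 in HckCA; the cause was not tested. With one start of the clustering, the counts were 11 (HckKO, tumour or mesenchymal-like), 519 (HckCA, macrophage-like) and 1 (Day14, macrophage-like), and Hck was at -0.12 in HckCA, where 0 to 4 cells per HckCA and WT_CA library were monocyte-like; the cause was not tested. With each experiment clustered alone, 3 genes passed for HckKO in tumour or mesenchymal-like cells and 1 class in share for HckCA. Stricter cells gave 1 gene (HckKO, tumour or mesenchymal-like), 12 (HckCA, T cell-like) and 2 classes in share (RK20449), doublets kept gave 1 gene (Day14, macrophage-like), and TMM factors on the class counts gave 2 classes in share (HckKO); the cause was not tested. Cells thinned to 2000 UMIs gave 84 (HckKO), 753 (HckCA) and 22 (Day14) genes in macrophage-like cells, and pooling with monocyte-like cells gave 5 (Day14). Without the HckKO and WT_KO libraries numbered 3, with fewer samples, 5, 3 and 17 genes passed in macrophage-like, T cell-like and tumour or mesenchymal-like cells. With an estimated correlation, 0 gene lists passed in macrophage-like cells in any of the 4 comparisons, and 0 sets of genes called in one comparison passed in another.

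Results that turned direction and passed in the main fit or the alternative are given by adjusted p, or by log2 value for genes. The cause was not tested. When genes below 0.25 times their level in another class were left out, chemokines in RK20449 macrophage-like cells (0.758) and collagens in RK20449 tumour or mesenchymal-like cells (0.5002) did so. Interferon gamma response in HckKO tumour or mesenchymal-like cells did so without HckKO 2 (left-out range 3.114e-30 to 0.887), proliferation in HckCA macrophage-like cells with one start of the clustering (0.0454), and T cell activation in HckCA macrophage-like cells with doublets kept (0.862). Hypoxia and glycolysis did so without Day10 1 in Day14 macrophage-like (0.568, range 5.24e-25 to 0.568) and T cell-like cells (0.107, range 5.175e-11 to 0.1442). In Day14 T cell-like cells, type I interferon response did so without Day14 2 (0.707, range 2.367e-23 to 0.707) and cytotoxic effector genes without Day10 2 (0.893, range 9.603e-09 to 0.893). H2-DMa (-0.0417) and H2-DMb2 (-0.1745) did so in HckCA macrophage-like cells at Leiden resolution 0.5.

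Leaving out each library in turn gave ranges, with fewer samples. For RK20449 the genes that passed were 478 to 1664 in macrophage-like, 26 to 46 in T cell-like and 617 to 2330 in tumour or mesenchymal-like cells, with 0 to 1 classes in share, 13 to 17 gene lists and Hck at -0.952 to -0.7837. For HckKO they were 50 to 275, 4 to 82 and 0 to 66, with 0 to 1 classes, 4 to 15 lists and Hck at -0.7207 to -0.5114. For HckCA they were 568 to 1849, 23 to 118 and 398 to 3244, with 0 to 0 classes, 15 to 17 lists and Hck at -0.01599 to 0.09281. For Day14 they were 0 to 304, 0 to 8 and 34 to 414, with 0 to 0 classes, 8 to 22 lists and Hck at -0.2049 to 0.1052.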

Other observations

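The counts of splits for genes, gene lists and shares, the tests of neighbouring genes around Hck and of wild-type Cd74, the monocyte-like genes and the T cell subsets were chosen after the results were seen. The tests by pooled classes, by thinning and on segments away from Hck were added after the first results, though before their own values were seen, and the splits for genes called in one comparison and tested in the other were set before.

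Regulatory T cells were a lower share of all cells in RK20449 than in Vehicle libraries, at 0.127% ± 0.133 (SD, n = 3) against 0.575% ± 0.118 (SD, n = 3), a log2 change of -2.20 (SE 0.65, adjusted p = 0.0141, edgeR; exact permutation p = 0.1). This did not pass without Vehicle 2 or RK20449 1 or 3 (adjusted p = 0.0513 to 0.164). The RK20449 mean became 0.0511% without RK20449 2. Of T cell-like cells, they were 4.20% ± 2.90 against 9.60% ± 2.54 (SD, n = 3 each) and did not pass (adjusted p = 0.0936), but did without RK20449 2 (0.0237).

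Monocyte-like cells, tested after the other classes had been seen, changed as well; their genes were chosen after their values were seen. With RK20449, 382 of 11126 genes passed (170 up, 212 down); Mthfd1, a folate enzyme, rose by 1.79 (adjusted p = 5.33e-06), Cd209a, a lectin of monocyte-derived dendritic cells, changed by -2.26 and Klf2 by -1.17. The count was 103 without Vehicle 2, 602 without Vehicle 3, 199 without RK20449 1, 193 without RK20449 2 and 135 without RK20449 3, and 122 with the experiment clustered alone and 921 without the filter on low counts. In HckKO, 65 of 10225 passed. Pde4d rose by 3.17, against 3.48 in macrophage-like cells, and was at -0.01 in tumour or mesenchymal-like cells (adjusted p = 0.992). Colec12, a scavenger receptor, rose by 2.38 and Slc7a11, a cystine transporter, by 1.50, and Egln3 changed by -1.89 but did not pass with the experiment clustered alone (adjusted p = 0.120). The count was 30 without WT_KO 2, 40 without WT_KO 3 and 220 without HckKO 2, 142 with the replicate number as a block and 354 without the filter. In HckCA, 843 of 10729 passed; Ciita, the master regulator of MHC class II, rose by 2.72 (adjusted p = 9.2e-05) and Arsb by 2.65, and Vcan changed by -2.01. That count was 204 without WT_CA 1, 104 without WT_CA 2, 1353 without HckCA 1, 442 with the experiment clustered alone and 269 with DESeq2. On day 14, 6 of 12395 passed; Ly6c2, a marker of inflammatory monocytes, rose by 1.76 and Mertk, a receptor for apoptotic cells, changed by -0.96, the latter not passing with the experiment clustered alone (adjusted p = 0.129). The 6 became 11 without Day10 1, 25 without Day10 2, 500 without Day14 1 and 479 without Day14 2. With other settings it was 612 without the filter, 104 with DESeq2, 34 with one start of the clustering, 25 with the replicate block, 23 with doublets kept, 11 with stricter cells and 20 when genes below 0.25 times their level in another class were left out.

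MHC class II genes were higher in HckCA than in WT_CA macrophage-like cells, with a median log2 change of 3.416 over the list. Cd74 and the median were both at 4.367 with cells thinned to 2000 UMIs. Random thinning keeps the expected share of each gene in a cell, so this could not decide whether depth is a cause. Classes were set before thinning, so an effect of depth on their boundary was not tested. A boundary between macrophage-like and monocyte-like classes that sits differently in the groups may account for part of the rise. In the pooled sums the median was 1.304. Cd74 went from 4.20 to 1.60 (adjusted p = 0.0760). A difference between sets of mice cannot be told apart from the allele, since Cd74 was at 5400 ± 1190 CPM in WT_KO and 424 ± 17.7 in WT_CA without TMM factors, a log2 ratio of 3.671. The active kinase may still favour MHC class II in these cells, as a hypothesis that more mice per genotype would test.

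Genes called in HckKO macrophage-like cells gathered near Hck, at 5.14 times the share of tested genes within 20 Mb (17 of 173), as a passenger segment of another strain around the altered gene would give. Of the 156 called genes elsewhere, 54 had another called gene within 1 Mb, against a median of 35 in a permutation test of 10000 draws (p = 0.0047), which leaves strain segments elsewhere as a candidate explanation for part of them. Pianp, with C1rb and Eno2 called within 1 Mb, is one of the 54; Pde4d had no other called gene within 1 Mb, and a passenger variant in it was not tested. A role of Hck itself in these genes was not tested.

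For the 6 libraries of RK20449 and Vehicle, and likewise of HckKO and WT_KO, the 10 splits are too few for a share under 0.05. With RK20449, 1 of the 10 splits gave as many genes in macrophage-like (1169, highest other 0), T cell-like (34, highest other 1) and tumour or mesenchymal-like cells (2009, highest other 0), and 1 as many classes in share (1, highest other 0). As many gene lists passed in 2 splits in macrophage-like (14, highest other 18), 1 in T cell-like (16, highest other 9) and 3 in tumour or mesenchymal-like cells (20, highest other 24). With HckKO, 1 split gave as many genes in macrophage-like (173, highest other 0), T cell-like (20, highest other 0) and tumour or mesenchymal-like cells (7, highest other 1), and all 10 as many classes in share (0, highest other 0). As many gene lists passed in 9 splits in macrophage-like (6, highest other 12), 4 in T cell-like (9, highest other 11) and 6 in tumour or mesenchymal-like cells (12, highest other 17). Where all 3 same-numbered pairs deviated together, 4 of the 10 splits part every pair as the real one does and the others part 1 pair. Among the 4, the highest other for genes and for lists was 0 and 19 with RK20449 in tumour or mesenchymal-like cells, 0 and 6 with HckKO in T cell-like cells, and 0 and 17 with HckKO in tumour or mesenchymal-like cells. For genes called in one comparison and tested in the other, the camera p of the RK20449 rises in HckKO was matched in 4 splits (0.0282, smallest other 1.95e-06), of the RK20449 falls in HckKO in 9 (0.442, smallest other 3.9e-09), of the HckKO rises in RK20449 in 7 (0.457, smallest other 0.00153) and of the HckKO falls in RK20449 in 8 (0.521, smallest other 6.54e-05).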
